A study of Mus musculus with 27 samples.

How the data were processed

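RNA was measured in 27 mouse samples in 10 groups, all with 28 days of angiotensin II (Ang II) infusion and with C57BL/6 as the labelled strain background. Bulk RNA sequencing covered 23 libraries in 4 count tables: non-stripped aorta (3 Cre, 3 TKO), stripped aorta (4 Cre, 2 TKO), isolated aortic fibroblasts (3 Cre, 3 TKO), and non-stripped TKO aorta given control IgG (3) or an anti-IL-9 antibody (2). Single-cell RNA sequencing covered 4 libraries of digested non-stripped aorta (2 Cre, 2 TKO). Samples were grouped by the genotype, treatment and tissue fields of their labels. The labels do not define Cre or TKO. The titles of the stripped samples carry the word nonstripped, while every other field of those labels says stripped, and the latter was followed.

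The bulk tables hold raw counts per gene symbol, as deposited: whole numbers whose totals differ between libraries. Trimmomatic 0.36, STAR 2.5.2b, featureCounts, Subread 1.5.2 and GRCm38 are listed for them in the submitters' processing notes, with no order, strand setting or annotation. RNA was harvested with Trizol, per the labels' protocols. The single-cell files hold UMI counts per gene and barcode from Cell Ranger 6.0.0, per the file headers. Their libraries used the 10x Genomics 3′ v3.1 dual-index chemistry and were sequenced in pairs, per the labels' protocols. Which libraries shared a run, and whether barcodes were filtered before deposit, is not given in the sources used here. The tables of group codes were not used here, and 1 column of per-sample values was not used because no label maps it. The row with no gene name held at most 0.0025% of a library's counts and was left out, and 27 symbols that a spreadsheet had turned into dates were kept as written.

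Total counts per bulk library ran from 17179257 to 38633457. The single-cell libraries held 114998 barcodes and 25922726 to 60910282 UMIs each. A count of 0 allows up to 3 counts of the total, intervals are 95% exact Clopper-Pearson or conditional binomial intervals, and both cover counting error only. The p-values of genes and class shares below measure the spread between samples. Those of gene lists, gene sets and Fisher's exact tests rest mainly on the spread across genes, which are not independent replicates. Where a gene had 5 or fewer counts over a group, the ratio of summed counts is given with its interval, and against a group at 0 it is given as a bound set by 3 counts over that group.

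The tests, samples, gene lists, cell type markers, the rule for named genes and most alternatives were chosen before the data were examined. Each bulk comparison used its own table only. Genes were filtered with filterByExpr (minimum count 10), scaled with TMM factors and tested with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by the quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. Every adjusted p for a gene comes from that test unless DESeq2 1.42.0 is named. A further contrast tested whether the genotype effect differed between non-stripped and stripped aorta, because each of those tissues has its own table and the tissues themselves cannot be compared. The deposited raw counts were scaled to library size with these factors (CPM), and levels are given as mean CPM ± SD. Log2 fold changes are given ± their standard error.

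The 29 gene lists (matrix, signalling, immune, muscle, metabolic and cell type genes, including tissues that a dissection could carry along) were tested with limma's camera at a preset correlation of 0.01 on lists with at least 5 tested members, with Benjamini-Hochberg adjustment over the lists of a comparison. List p-values in the report are these adjusted values. With a correlation estimated from the data, no list passed in any comparison, and that adjusted p is given with each call or group of calls. Members adjusted over the list alone are counted beside those adjusted over all genes. The 100 genes with the smallest p in each direction in non-stripped TKO aorta were carried to the other tables as sets, since fewer genes than planned were called. A further alternative with the called genes only was chosen after seeing the data.

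Named genes are Klf10, Il9 and Il9r, then per bulk comparison up to 8 per direction with the largest change among genes past the threshold, with a mean CPM of at least 1 and groups that do not overlap. Predicted genes, pseudogenes and antigen receptor segments were left out there, but not among the genes named per single-cell class, up to 3 per direction with the smallest adjusted p. Where fewer than 5 passed in a direction, the 5 with the smallest p stand in their place and are said not to pass. Up to 3 members of each described list are named by adjusted p. Some genes are not reported here. Gene positions come from the GENCODE vM21 annotation of GRCm38. The tables give no strand or identifiers beyond symbols, so overlapping genes, paralogs and pseudogenes that share reads are uncertain.

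Cells were kept with at least 500 genes, at least 1000 UMIs and at most 15% mitochondrial UMIs, which left 43812. Scanpy 1.11.5 chose 2000 variable genes, scaled cells to 10000 UMIs, and used 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, python-igraph 0.11.9) at resolution 1, with no integration. The doublet caller, Scrublet, marked 0 cells in each library although scores reached 0.611, so it did not work and no doublet was removed. An alternative without cells of a score over 0.15 was chosen after seeing the data. Of 37 clusters, 26 were named as 16 of the 22 marker classes. A name needed a mean marker fold of at least 1.5 on the log2 scale, at least 3 markers in at least 10% of cells, no other lineage scoring above 1, and a mean doublet score of at most 0.12. These limits were set after the clusters were seen. Class names are written as likenesses (T-like) since they rest on markers. Counts were summed per class and library for 14 classes with at least 50 cells in every library and tested with edgeR as above. The 17 class shares, unnamed cells included, were tested with edgeR on cells per library. With 2 libraries against 2, cells are not replicates.

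The scripts were tested on simulated data with 200 changed genes per comparison. The share of genes with a simulated 2-fold change that was recovered was 65.3% for non-stripped aorta, 54% for stripped aorta, 58% for fibroblasts, 44.9% for anti-IL-9 and 0% for fibroblast-like single cells. At 4-fold it was 89.6%, 83.3%, 95.9%, 77.6% and 67.3%. False calls were 9 of 144, 8 of 125, 12 of 151 and 12 of 122 calls in the bulk comparisons, in the same order. There were 6 in fibroblast-like and 24 in macrophage-like cells. Alternatives were DESeq2 with its own size factors, edgeR with RLE factors, no low-count filter, a joint fit over all 23 bulk libraries, an added limit of 1 on the absolute log2 fold change, and each library left out. For single cells they were also a stricter cell filter, a finer clustering at resolution 2 and the replicate number as a block.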

Results

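Aortic RNA was profiled in mice given Ang II, a hormone that raises blood pressure and drives scarring around vessels, for 28 days. The study asks about KLF10 and IL-9 in perivascular fibrosis, and compares mice labelled Cre and TKO, all on a C57BL/6 background. Bulk libraries of non-stripped aorta (3 Cre, 3 TKO) held 17359198 to 26998674 counts, those of stripped aorta (4 Cre, 2 TKO) 27029228 to 35936774, and those of isolated aortic fibroblasts (3 Cre, 3 TKO) 28174755 to 38633457. Non-stripped TKO aorta given IgG (3) or an anti-IL-9 antibody (2) held 17179257 to 22745977 counts. Mitochondrially encoded genes took 16.9% to 21.0% of counts in the non-stripped table, 3.16% to 9.11% in the stripped table, 0.796% to 0.970% in fibroblasts and 19.6% to 25% in the anti-IL-9 table. In 4 single-cell libraries, 14489 and 6533 Cre cells and 15365 and 7425 TKO cells were kept, with median depths of 2768, 1683, 1593 and 1409 UMIs. The labels do not say what stripping removed.

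Klf10, which encodes a zinc finger transcription factor induced by TGF-beta, was read in nearly every library. In non-stripped aorta its counts were 1049, 943 and 1400 in Cre and 822, 696 and 0 in TKO. TKO replicate 3, with 0 counts, is limited to 0.173 CPM. Klf10 RNA was thus mixed in this TKO group, and the labels do not say if genotype was too. No other gene in the 23 bulk libraries combined 0 counts in 1 library with at least 100 in every other library of its table. Mean Klf10 was 52.2 CPM ± 12.7 in Cre and 25.6 CPM ± 22.3 in TKO (log2 fold change −1.02 ± 0.97, adjusted p = 0.595), −0.44 (adjusted p = 0.368) without TKO replicate 3 and −1.55 without TKO replicate 1. In stripped aorta it was 45.1 CPM ± 13.6 against 28.9 CPM ± 11.8 (−0.64 ± 0.33, adjusted p = 0.436; −1.13 and −0.28 without TKO replicates 1 and 2). In fibroblasts Klf10 was 67.0 CPM ± 6.15 against 65.0 CPM ± 6.51 (−0.04 ± 0.10, adjusted p = 0.885), and the sign turned to 0.03 at the highest when a library was left out. In TKO aorta Klf10 was 38.5 CPM ± 9.52 with IgG and 22.1 CPM ± 1.82 with anti-IL-9 (−0.80 ± 0.22, adjusted p = 0.0296). That call was lost in the joint fit (adjusted p = 0.437), without IgG replicate 1 (0.064) and without anti-IL-9 replicates 1 (0.0847) or 2 (0.117). The labels name neither the cells meant to lack Klf10 nor the deleted part of the gene, so these levels check the labels only in part.

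**Figure D1:**
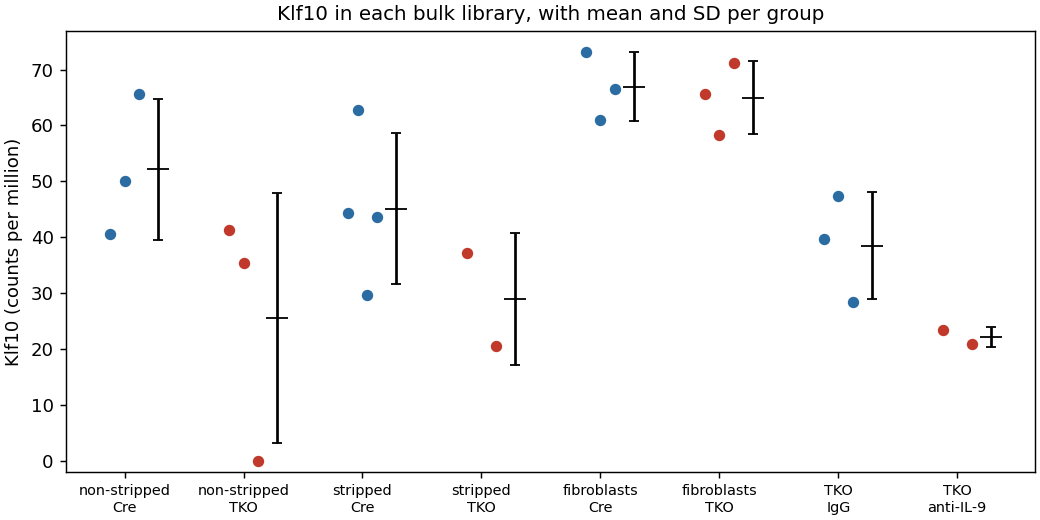
Klf10 in CPM (vertical axis) in each bulk library by group (horizontal axis), with points for libraries and bars for the mean and SD. TKO replicate 3 of non-stripped aorta lies at 0, while the other libraries of that table hold at least 696 counts.

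Il9, the gene of the cytokine that the antibody binds, had 0 counts in every bulk library except 1 count in fibroblast TKO replicate 1. At these depths a count of 0 allows between 0.0777 and 0.175 CPM. Il9r, its receptor, did not pass the test in any table that retained it, with 0.436 CPM ± 0.437 against 0.393 CPM ± 0.208 in non-stripped aorta (−0.14 ± 0.75, adjusted p = 0.939). It was at 0.182 CPM ± 0.143 against 0.296 CPM ± 0.0908 in fibroblasts (0.68 ± 0.57, adjusted p = 0.652) and at 0.515 CPM ± 0.151 against 0.548 CPM ± 0.698 with anti-IL-9 (0.17 ± 0.85, adjusted p = 0.896). The IL-9 and Th9 list, with receptor, JAK and STAT genes, passed in no bulk comparison. Its median was −0.12 in non-stripped aorta (adjusted p = 0.59), 0.11 in stripped aorta (0.218), 0.06 in fibroblasts (0.956) and −0.33 with anti-IL-9 (0.0858), where 1 of 15 members rose and 4 fell.

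Non-stripped aorta asks what the genotype changes in the whole vessel. Pdpr, a regulatory subunit of pyruvate dehydrogenase phosphatase, rose from 19.97 CPM ± 3.1 to 66.3 CPM ± 7.16 (1.73 ± 0.14, adjusted p = 0.00711, n = 3 per group). Eno1b, an enolase copy that may share reads with Eno1, rose from 8.89 CPM ± 0.787 to 466 CPM ± 215 (5.72 ± 0.34, adjusted p = 0.00198). Cdsn, which encodes the epidermal adhesion protein corneodesmosin, had 5 counts in Cre and 248 in TKO, a ratio of 58.6 (24.8 to 182; adjusted p = 0.0149). Cep85l (2.49 ± 0.29, adjusted p = 0.0276), Wdfy2 (1.77 ± 0.20, 0.0276), Rapgef5 (1.40 ± 0.18, 0.0387) and Prune2 (0.90 ± 0.10, 0.0276) rose too. Rpl30, a ribosomal protein gene with many pseudogenes, fell from 149 CPM ± 8.51 to 62.2 CPM ± 4.54 (−1.26 ± 0.10, adjusted p = 0.00691). H2-T24, a non-classical MHC class I gene, fell from 19.5 CPM ± 2.88 to 5.59 CPM ± 0.617 (−1.80 ± 0.16, adjusted p = 0.00925), and Ddr1, a collagen receptor kinase, from 32.6 CPM ± 2.51 to 17.2 CPM ± 1.37 (−0.92 ± 0.11, adjusted p = 0.0276). Wdfy1 (−1.32 ± 0.16, adjusted p = 0.0284), Polr2k, a subunit shared by the RNA polymerases (−0.94 ± 0.12, 0.0381), and Cpq, a carboxypeptidase gene (−0.72 ± 0.09, 0.0341), also fell. Cdsn, Ddr1 and H2-T24 start at 35552128, 35681567 and 36005695 of chromosome 17 (GRCm38).

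In all, 9 genes rose and 9 fell among 15162 tested by edgeR, with 2714 at an unadjusted p under 0.05, and DESeq2 called 802, which included all 18. The calls rest on single libraries. They numbered 4, 1 and 0 without Cre replicates 1, 2 and 3, 10 without TKO replicate 1, 486 without TKO replicate 2 and 224 without TKO replicate 3. Each of the 13 named genes lost its call without at least 1 library, with adjusted p between 0.0532 and 0.193, while 0 turned in direction.

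Among the gene lists in non-stripped TKO aorta, skeletal muscle genes stood out. Their median was 3.27 with 16 of 16 positive, 0 called over all genes and 16 higher when adjusted over the list alone (adjusted p = 6e-28, and adjusted p = 0.706 with an estimated correlation). Myh4, a fast myosin, had 54.6 CPM ± 30.3 in Cre and 1242 CPM ± 1059 in TKO (4.51 ± 0.72, adjusted p = 0.0592), and Pvalb (3.67 ± 0.63, 0.0669) and Mylpf (3.22 ± 0.59, 0.0729) did not pass either. Cardiac muscle genes had a median of 1.51 with 7 of 8 positive and 5 higher over the list alone (adjusted p = 0.00373; adjusted p = 0.706 with an estimated correlation), with Myl2 at 3.01 ± 0.79 and Myh7 at 3.28 ± 0.94 (1.71 and 2.11 without TKO replicate 3). Muscle carried along in dissection was not ruled out here or below. Endothelial markers had a median of −0.19, 12 of 15 negative and 6 lower over the list alone (adjusted p = 0.00373; adjusted p = 0.706 with an estimated correlation; −0.10 without Cre replicate 3 or TKO replicate 2). Cldn5, a tight junction gene, was at −0.59 ± 0.12 (adjusted p = 0.0803), Cdh5 at −0.47 ± 0.11 and Tie1 at −0.42 ± 0.10. Oxidative phosphorylation genes were all negative, 34 of 34, with a median of −0.21 and 0 adjusted over the list alone (adjusted p = 3.64e-05; adjusted p = 0.885 with an estimated correlation; −0.12 without Cre replicate 1). Other splits of these 6 libraries, which mix the genotypes, called up to 16 lists, against 9 here.

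Circadian clock genes had a median of 0.82, 13 of 16 positive and 6 higher over the list alone (adjusted p = 0.0106; adjusted p = 0.706 with an estimated correlation). Dbp was at 3.22 ± 0.94 (adjusted p = 0.132), Per2 at 2.43 ± 0.70 and Bhlhe41 at 1.32 ± 0.37, and without TKO replicate 1 the list lost its call (0.45, adjusted p = 0.213) and Per2 was at 1.60. Mesothelial markers had a median of −0.44, 7 of 8 negative (adjusted p = 0.0106; adjusted p = 0.706 with an estimated correlation; 0.0703 without Cre replicate 3 and 0.083 without TKO replicate 2), with Upk3b at −0.47 ± 0.13. Fatty acid oxidation genes had a median of −0.22, 16 of 19 negative (adjusted p = 0.0155; adjusted p = 0.885 with an estimated correlation; −0.12 and 0.151 without Cre replicate 1 and 0.136 without TKO replicate 2). Contractile smooth muscle genes split. The list was called lower with a median of −0.32 and a mean of 0.07 (adjusted p = 0.0167; adjusted p = 0.885 with an estimated correlation), with 5 higher and 9 lower over the list alone. The smooth muscle myosin Myh11 was at −0.90 ± 0.16 (adjusted p = 0.0729) and Itga8 at −1.48 ± 0.31, against 2.08 ± 0.43 for Tpm1, a tropomyosin also used by striated muscle (0.0779; 1.33 without TKO replicate 3). That call was lost without TKO replicate 1 (0.449), 2 (0.136) or 3 (0.175). Mitochondrially encoded genes had a median of −0.19, 9 of 9 negative (adjusted p = 0.0332; adjusted p = 0.885 with an estimated correlation), and lost the call without Cre replicates 1 (0.151) or 2 (0.0613) or TKO replicate 1 (−0.13, 0.311).

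The matrix lists did not pass in non-stripped aorta. Collagens had a median of 0.09 and a test direction of lower (11 of 19 positive, adjusted p = 0.911), other extracellular matrix genes 0.15 (21 of 34 positive, adjusted p = 0.59), and crosslinking and remodelling genes 0.03 with a test direction of lower (adjusted p = 0.911). Adjusted over the list alone, 2 matrix genes were lower: Emilin1 (−0.51 ± 0.12, adjusted p = 0.0868 over all genes) and elastin, Eln, at 136 CPM ± 38.0 against 74.2 CPM ± 10.4 (−0.87 ± 0.21, 0.0877). Col18a1 was at −0.62 ± 0.21 (adjusted p = 0.181; −0.35 without Cre replicate 1) and Col12a1 at 0.61 ± 0.22 (0.201; 0.36 without TKO replicate 3). TGF-beta signalling had a median of 0.05 (adjusted p = 0.59), T cell markers −0.44 (0.225), interferon response 0.01 with a mean of −0.0024 (0.629), MHC class II −0.17 (0.188), erythrocyte markers 0.36 (0.59), and immediate early and dissociation stress genes 0.06 with a mean of −0.01 (0.328).

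**Figure D2:**
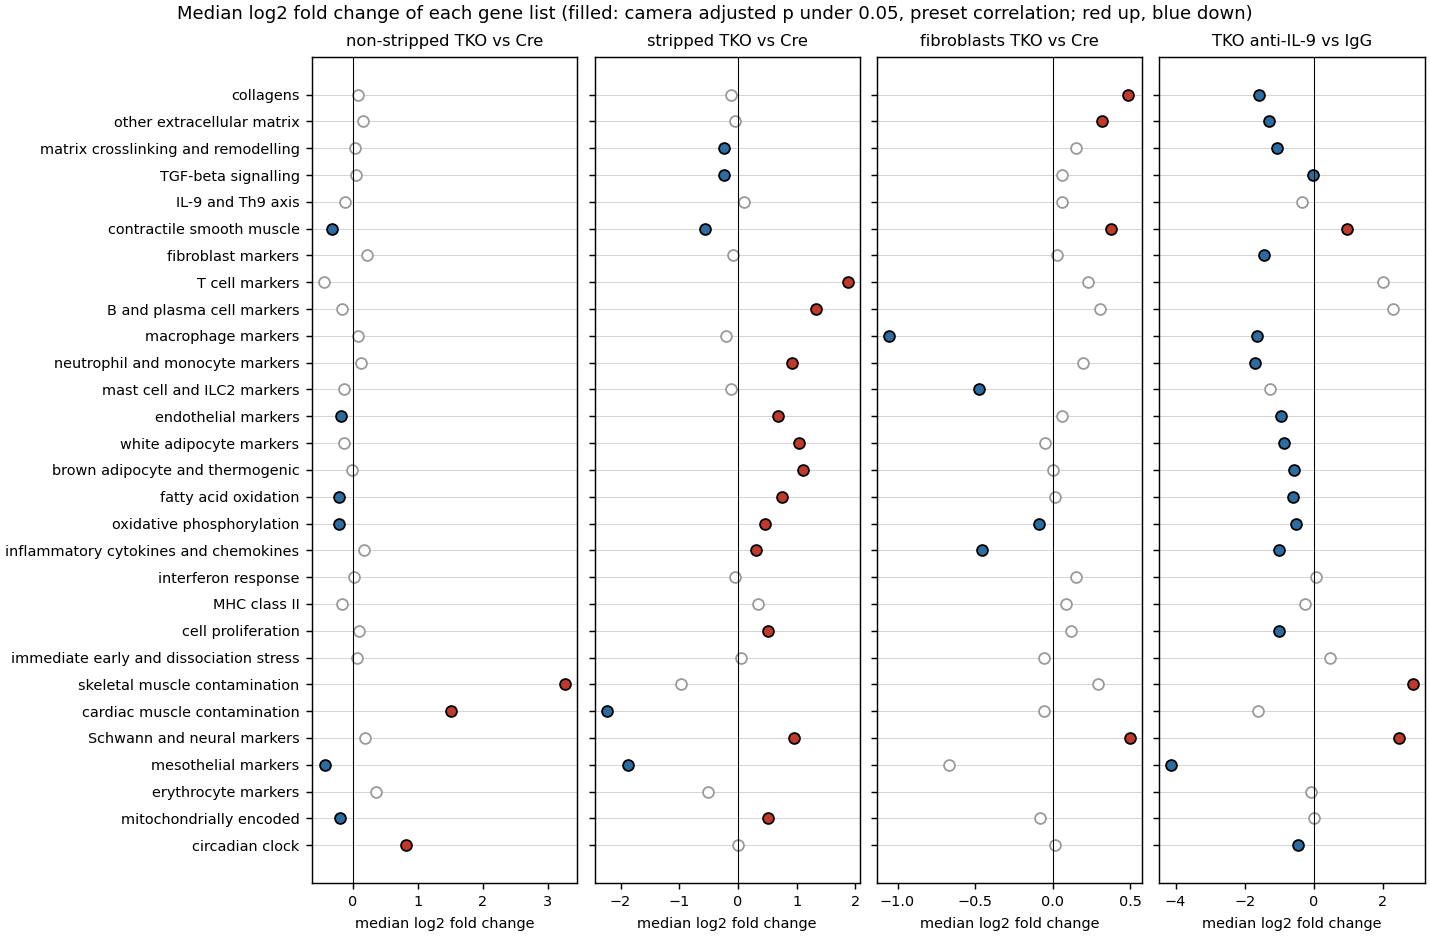
Median log2 fold change (horizontal axis) of each gene list (vertical axis) in the 4 bulk comparisons, with filled points for lists past the adjusted p of 0.05 at the preset correlation. Skeletal muscle genes reach 3.27 in non-stripped aorta, macrophage markers −1.05 in fibroblasts and mesothelial markers −4.12 with anti-IL-9.

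Stripped aorta asks the same of the vessel after stripping. Slc7a11, the cystine-glutamate exchanger, rose from 0.327 CPM ± 0.12 to 6.18 CPM ± 0.720 (4.24 ± 0.35, adjusted p = 0.0209, 4 Cre and 2 TKO). Unc5b, a netrin receptor gene of vessels, fell from 72.2 CPM ± 3.80 to 32.1 CPM ± 1.39 (−1.17 ± 0.09, adjusted p = 0.0209), and Myrf, which encodes the myelin regulatory factor, from 21.9 CPM ± 1.55 to 7.73 CPM ± 0.607 (−1.50 ± 0.13, adjusted p = 0.0209). Gm14150, a predicted gene chosen after its values were seen, rose from 0.265 CPM ± 0.0787 to 4.52 CPM ± 0.0447 (4.07 ± 0.33, adjusted p = 0.0209). Of the genes named by p that did not pass, Pnpla2, the triglyceride lipase of fat cells, was at 191 CPM ± 25.8 and 496 CPM ± 27.0 (1.37 ± 0.14, adjusted p = 0.0527). Bnip3 (0.88 ± 0.10), Cpt2 (0.78 ± 0.09), Hp (1.33 ± 0.16), the Notch target Heyl (−1.16 ± 0.14), Gpr137b (−0.96 ± 0.12) and Hpgd (−0.79 ± 0.10) were each at an adjusted p of 0.0718. edgeR called 2 genes higher and 2 lower among 16688, with 2295 at an unadjusted p under 0.05, and DESeq2 called 538, which included all 4. The calls numbered 4, 0, 0 and 23 without Cre replicates 1 to 4, and 30 and 7 without TKO replicates 1 and 2. Each of the 4 genes lost its call without at least 1 library (adjusted p 0.0522 to 0.107).

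In stripped TKO aorta 4 lists of fat and mitochondrial genes were called higher at the preset correlation, with 0 members called over all genes by edgeR. Cre replicate 1 lay below the other Cre libraries, with 21.9 CPM of Ucp1 against 97.3 to 109.6 CPM and a mean log2 CPM of 5.90 against 6.34 to 6.37 for fatty acid oxidation genes. Fatty acid oxidation genes had a median of 0.76, 19 of 19 positive and 17 higher when adjusted over the list alone (adjusted p = 3.13e-25; adjusted p = 0.278 with an estimated correlation). Acadvl was at 0.77 ± 0.11 (adjusted p = 0.101) and Slc25a20 at 0.91 ± 0.16. White adipocyte markers had a median of 1.04, 16 of 16 positive and 12 higher over the list alone (adjusted p = 4.77e-21; adjusted p = 0.278 with an estimated correlation). Lipoprotein lipase, Lpl, was at 595 CPM ± 133 and 1417 CPM ± 92.9 (1.25 ± 0.21, adjusted p = 0.113) and Lipe at 1.22 ± 0.22. Brown adipocyte genes had a median of 1.10, 12 of 14 positive, with 9 higher and 1 lower over the list alone (adjusted p = 4.94e-09; adjusted p = 0.278 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, was at 82.0 CPM ± 40.4 and 383 CPM ± 26.5 (2.22 ± 0.51, adjusted p = 0.191), and Otop1 at 1.53 ± 0.29. Oxidative phosphorylation genes had a median of 0.45, 34 of 34 positive and 0 over the list alone (adjusted p = 1.45e-15; adjusted p = 0.368 with an estimated correlation). Schwann and neural markers had a median of 0.96, 12 of 12 positive and 3 higher over the list alone (adjusted p = 9.68e-08; adjusted p = 0.368 with an estimated correlation), with Cdh19 at 1.17 ± 0.23.

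The lists of mesothelial markers and contractile genes were called lower at that correlation, also with 0 members over all genes. Mesothelial markers had a median of −1.87, 8 of 8 negative and 5 lower over the list alone (adjusted p = 1.1e-12; adjusted p = 0.278 with an estimated correlation). Upk1b was at −3.00 ± 0.40 (adjusted p = 0.092), Msln at −2.07 ± 0.30 (0.101) and Upk3b at −2.22 ± 0.37 (0.117). Contractile smooth muscle genes had a median of −0.56, 18 of 18 negative and 4 lower over the list alone (adjusted p = 7.47e-11; adjusted p = 0.368 with an estimated correlation). Smtn was at −0.64 ± 0.16, Tagln at −0.64 ± 0.17 (−0.40 without TKO replicate 1) and Tpm1 at −0.74 ± 0.22. These 7 lists passed at the preset correlation whichever library was left out, but some medians moved. The contractile median was −0.25 without TKO replicate 1 and −0.93 without TKO replicate 2, and without TKO replicate 2 oxidative phosphorylation was at 0.23 and Schwann and neural markers at 0.57.

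Another 10 lists passed in stripped aorta but rested on single libraries. T cell markers had a median of 1.87, 15 of 17 positive and 9 higher over the list alone (adjusted p = 1.1e-06; adjusted p = 0.368 with an estimated correlation), and without TKO replicate 2 a median of 0.06 (adjusted p = 0.971). Trbc2, a T cell receptor constant gene, was at 1.15 CPM ± 0.441 and 18.9 CPM ± 24.4 (4.03 ± 0.93, adjusted p = 0.191; 0.54 without that replicate). B and plasma cell markers had a median of 1.32, 9 of 11 positive and 4 higher over the list alone (adjusted p = 1.41e-05; adjusted p = 0.368 with an estimated correlation), without TKO replicate 2 a median of −0.05 (adjusted p = 0.187) and without TKO replicate 1 a median of 2.03, with the antibody gene Igkc at 3.44 ± 0.52 (adjusted p = 0.102). Without that replicate the calls were also lost for proliferation (0.52, 17 of 20 positive, adjusted p = 4.29e-05; 0.0877 without it), matrix crosslinking (−0.24, 24 of 30 negative, 0.00482; 0.168; −0.36 without TKO replicate 1), TGF-beta signalling (−0.23, 15 of 23 negative, 0.00493; 0.141), endothelial markers (0.69, 11 of 15 positive, 0.00616; 0.09, 0.583), neutrophil and monocyte markers (0.92, 8 of 8 positive, 0.0202; −0.08, 0.971), cytokines and chemokines (0.31, 21 of 27 positive, 0.0202; 0.19, 0.156), cardiac muscle (−2.24, 9 of 10 negative, 0.0202; −1.47, 0.358; −3.81 without TKO replicate 1) and mitochondrially encoded genes (0.51, 9 of 9 positive, 0.0333; −0.12, 0.762; 0.89 without TKO replicate 1). Over these 8, adjusted p = 0.368 to 0.72 with an estimated correlation. Without Cre replicate 1 the endothelial (0.45, 0.0782) and mitochondrially encoded (0.32, 0.258) calls were lost, without Cre replicate 3 the neutrophil (0.0516) and cardiac (−0.96, 0.313) calls, and without Cre replicate 4 the cytokine (0.0541) and cardiac (0.0541) calls. Collagens (median −0.11, adjusted p = 0.231), other extracellular matrix genes (−0.06 with a mean of 0.04, 0.924), macrophage markers (−0.20, 0.0845) and fibroblast markers (−0.09, 0.633) did not pass. Without TKO replicate 1 the matrix list was called lower (−0.26, adjusted p = 0.032) and the immediate early list higher (0.63, 0.042; with every library 0.06, mean −0.02, 0.335). MHC class II had a median of 0.34 (0.111), interferon response −0.06 (0.335) and erythrocyte markers −0.52 (0.174).

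The genotype effect was then compared between both tissues. Pdpr was the only gene whose effect differed, by 1.92 on the log2 scale (non-stripped minus stripped, adjusted p = 0.035), among 17501 tested by edgeR, with 3178 at an unadjusted p under 0.05. DESeq2 called 878. The single call was lost without any of the 3 non-stripped Cre libraries, without non-stripped TKO replicate 2 and without stripped Cre replicates 2 or 3, each leaving 0 genes higher, and up to 99 genes higher and 143 lower were called without another library. Tissue and table are confounded, but the genotypes lie within each table.

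Isolated fibroblasts ask what the genotype changes in the cells that lay down matrix. Matn2, which encodes the matrix adaptor matrilin, rose from 11.3 CPM ± 0.534 to 22.6 CPM ± 1.13 (1.01 ± 0.09, adjusted p = 0.0139, n = 3 per group). Rpl30 fell from 506 CPM ± 57.0 to 190 CPM ± 5.81 (−1.42 ± 0.10, adjusted p = 0.00217). Polr2k fell from 20.6 CPM ± 2.26 to 9.11 CPM ± 0.425 (−1.18 ± 0.11, 0.0146), and Deptor, an inhibitor of mTOR, from 16.7 CPM ± 0.718 to 8.26 CPM ± 0.627 (−1.01 ± 0.11, 0.0219). Hddc3 (−2.07 ± 0.22, adjusted p = 0.0196) and AU020206 (−1.46 ± 0.14, 0.0139) fell too. Outside the naming rule, and chosen after their values were seen, 4 predicted genes rose whose reads may be shared with their parent genes. Gm14150 went from 0.609 CPM ± 0.247 to 28.2 CPM ± 4.19 (5.54 ± 0.25, adjusted p = 0.000265), Gm3756 rose by 4.26 ± 0.21 (0.000265), Gm6682 by 3.47 ± 0.32 (0.0139), and Gm14287 had 5 counts in Cre and 379 in TKO, a ratio of 74.4 (31.6 to 230; adjusted p = 0.0153). Col4a5, a basement membrane collagen (0.81 ± 0.10, adjusted p = 0.0671), Rspo2, a Wnt agonist (2.17 ± 0.30, 0.0832), Ankrd46 (0.51 ± 0.07, 0.0832) and Lurap1l (0.61 ± 0.08, 0.0832) did not pass. edgeR called 5 genes higher and 5 lower among 15673, with 1898 at an unadjusted p under 0.05, and DESeq2 called 417, which included all 10. The calls numbered 4, 10 and 5 without Cre replicates 1, 2 and 3, and 4, 3 and 5 without TKO replicates 1, 2 and 3. Rpl30, Gm14150 and Gm3756 stayed called without any 1 library, and the other 7 lost the call without at least 1 (adjusted p 0.0512 to 0.152).

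In TKO fibroblasts, of untested purity, macrophage markers were called lower and 2 matrix lists higher. The former had a median of −1.05, 16 of 16 negative and 12 lower over the list alone (adjusted p = 1.46e-14; adjusted p = 0.741 with an estimated correlation). Cd14, the lipopolysaccharide co-receptor, was at 55.1 CPM ± 20.4 and 22.5 CPM ± 6.10 (−1.29 ± 0.27, adjusted p = 0.217), and Pf4 at −1.07 ± 0.23. Collagens had a median of 0.49, 16 of 19 positive and 2 higher over the list alone (adjusted p = 1.36e-07; adjusted p = 0.761 with an estimated correlation). Col8a1 was at 169 CPM ± 42.3 and 305 CPM ± 9.59 (0.85 ± 0.17, adjusted p = 0.208) and Col6a3 at 0.49 ± 0.12 (0.238). Other extracellular matrix genes had a median of 0.32, 31 of 35 positive and 1 higher over the list alone (adjusted p = 2.09e-08; adjusted p = 0.741 with an estimated correlation). The collagen-binding Fmod was at 0.84 ± 0.13 (adjusted p = 0.114), Comp at 0.55 ± 0.13 and Ogn at 0.76 ± 0.21. Contractile genes had a median of 0.38, 17 of 18 positive and 3 higher over the list alone (adjusted p = 5.1e-07; adjusted p = 0.741 with an estimated correlation), with Myocd at 1.49 ± 0.32 and Lmod1 at 0.94 ± 0.25. These 4 lists passed at the preset correlation whichever library was left out. No member passed over all genes. Without Cre replicate 2 medians were −0.58 (macrophage) and 0.18 (other matrix). Other splits of these 6 libraries called up to 14 lists, against 8 here.

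Schwann and neural markers (median 0.50, 8 of 9 positive, adjusted p = 0.00204; 0.32, 0.0562 without TKO replicate 3) and mast cell and ILC2 markers (−0.47, 8 of 9 negative, 0.00222; −0.05, 0.148 without Cre replicate 3 and −0.81 without Cre replicate 1) passed in fibroblasts, each at adjusted p = 0.863 with an estimated correlation. Il1rl1, the IL-33 receptor, was at −0.84 ± 0.14 (adjusted p = 0.125). Oxidative phosphorylation genes (−0.09, 30 of 34 negative, adjusted p = 0.0167; adjusted p = 0.974 with an estimated correlation) lost the call without Cre replicates 1 (0.249) or 2 (−0.04, 0.315) or TKO replicates 2 (0.0912) or 3 (0.0988). Cytokines and chemokines (−0.45, 19 of 27 negative, adjusted p = 0.036; adjusted p = 0.974 with an estimated correlation) turned to 0.11 (0.749) without Cre replicate 3 and lost the call without TKO replicate 3 (−0.25, 0.506), with Ccl5 at −0.95 ± 0.29 (−0.57 without Cre replicate 2). Crosslinking and remodelling genes (0.15, 5 higher and 3 lower over the list alone, adjusted p = 0.198) and TGF-beta signalling (0.06 with a mean of −0.02, 2 higher and 3 lower, 0.932) did not pass, with Tgfb2 at 0.78 ± 0.13 (0.125) and Tgfb3 at 0.73 ± 0.14 (0.184). Fibroblast markers (0.03, adjusted p = 0.932), T cell markers (0.23, 17 of 17 positive, 0.112), interferon response (0.15, 0.956) and MHC class II (0.09 with a test direction of lower, 0.956) did not pass.

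Some called genes lie near Klf10, at 38291463 to 38300706 of chromosome 15 (GRCm38): Rpl30 starts at 34440505, Polr2k at 36174010 and Matn2 at 34306677, with Cpq at 33083129 and Deptor at 55112317. Within 20 Mb to either side of Klf10, a window chosen after the calls were seen, 37 of 94 tested genes (39.4%) had an unadjusted p under 0.05 in fibroblasts, against 12% elsewhere (odds ratio 4.77, Fisher's exact test, p = 1.7e-11). In non-stripped aorta these were 34.8% against 17.9% (odds ratio 2.46, Fisher's exact test, p = 0.000105), and in stripped aorta 29.4% against 13.7% (2.62, Fisher's exact test, p = 3.3e-05). With anti-IL-9, where both groups are TKO, they were 49.5% against 43.9% (1.25, Fisher's exact test, p = 0.163). In single cells the share was 12.8% against 4.79% in fibroblast-like and 12% against 2.65% in endothelial-like cells, but 5.77% against 5.12% in B-like and 3.125% against 4.83% in plasma-like cells. Genes are not independent replicates.

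**Figure D3:**
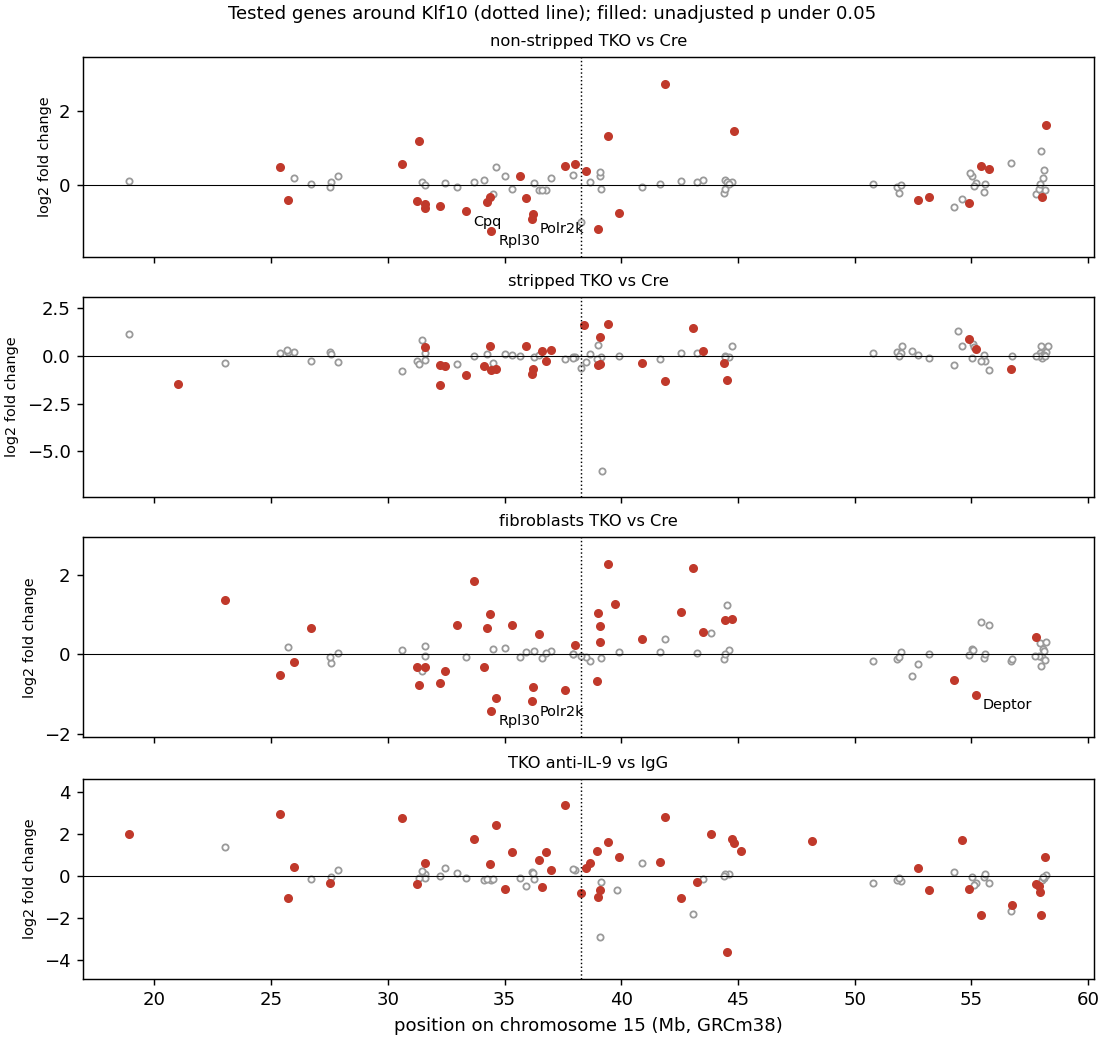
Log2 fold change (vertical axis) of each tested gene by its position in Mb on chromosome 15 (horizontal axis, GRCm38) within 20 Mb of Klf10 (dotted line) in the 4 bulk comparisons, with filled points for an unadjusted p under 0.05. In fibroblasts 37 of 94 genes are filled, among them Rpl30 at −1.42 and Polr2k at −1.18.

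Anti-IL-9 against IgG in TKO aorta asks what blocking IL-9 changes. Neural genes were much higher after the antibody. Htr3a and Htr3b, subunits of the serotonin-gated channel, rose from 11.3 CPM ± 8.42 to 354 CPM ± 92.3 (4.97 ± 0.57, adjusted p = 0.00083, n = 3 and 2) and from 2.29 CPM ± 1.48 to 82.2 CPM ± 12.6 (5.16 ± 0.41, 0.000201). The sympathetic neuropeptide gene Npy rose from 24.5 CPM ± 23.7 to 722 CPM ± 55.9 (4.88 ± 0.73, 0.00276). The purine receptor P2rx2 rose by 4.87 ± 0.44 (0.000294) and the dopamine receptor Drd2 by 4.80 ± 0.60 (0.00122). Hoxc10 had 5 counts with IgG and 205 with the antibody, a ratio of 56.4 (23.8 to 176; adjusted p = 0.000755), and Nr1h5 had 3 and 149, a ratio of 68.3 (22.9 to 335; 0.00148). Mesothelial genes fell: mesothelin, Msln, from 57.3 CPM ± 31.8 to 0.956 CPM ± 0.347 (−5.86 ± 0.59, 0.00046), and Upk3b from 77.8 CPM ± 39.8 to 1.82 CPM ± 1.34 (−5.35 ± 0.61, 0.000794). So did Upk1b (−5.26 ± 0.74, 0.00208; −8.09 without anti-IL-9 replicate 1), Lrrn4 (−4.62 ± 0.53, 0.000783) and the keratin Krt7 (−3.84 ± 0.59, 0.00295). Bnc1 had 280 counts with IgG and 5 with the antibody, 40.7-fold lower with an interval of 17.2 to 126 (0.000177). Krt14 (−5.10 ± 0.93, 0.00627; 0.0585 without anti-IL-9 replicate 1) and the endocytic receptor Lrp2 (−3.80 ± 0.43, 0.000791) fell too. Cr2, a complement receptor of B cells (4.90 ± 1.11, 0.0155), lost the call without IgG replicate 3 (0.0555) and without anti-IL-9 replicate 1 (2.53, 0.158).

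edgeR called 3462 genes higher and 1815 lower with anti-IL-9 among 16463, and DESeq2 called 5588. The lower count moved to 1115 without IgG replicate 3, to 1048 without anti-IL-9 replicate 1, to 2892 with no low-count filter and to 2757 in the joint fit. Of the lower genes, 647 had a fold change of at least 1 on the log2 scale.

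**Figure D4:**
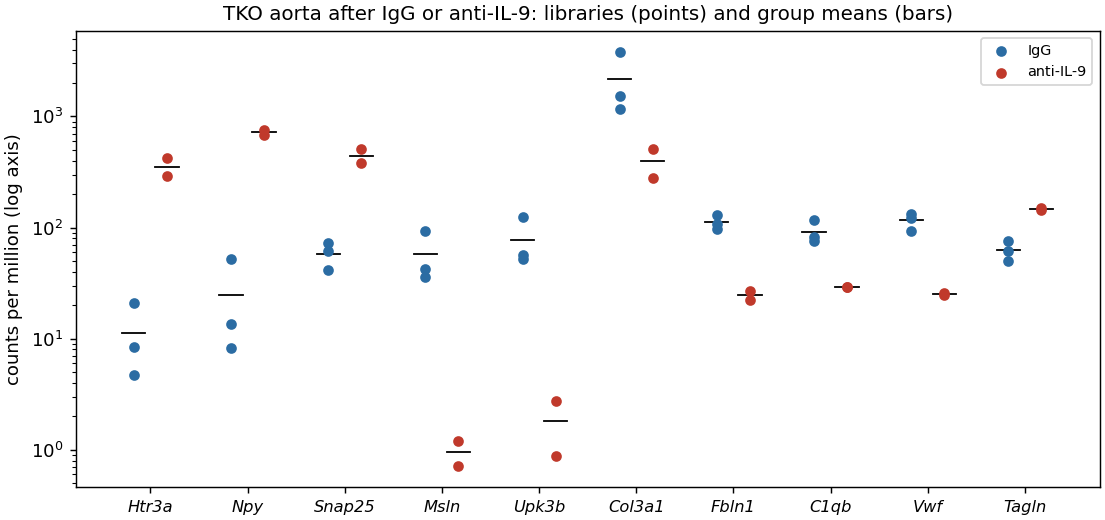
CPM on a log axis (vertical) of 10 genes (horizontal axis) in TKO aorta after IgG (3 libraries) or anti-IL-9 (2), with points for libraries and bars for group means. Htr3a, Npy and Snap25 are higher with the antibody, and Msln, Upk3b, Col3a1, Fbln1, C1qb and Vwf lower, by −5.86 for Msln.

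By gene list, Schwann and neural markers rose, with a median of 2.46, 10 of 12 higher over all genes and 11 over the list alone (adjusted p = 2.94e-10; adjusted p = 0.617 with an estimated correlation). Snap25, of the synaptic release machinery, went from 58.2 CPM ± 15.5 to 444 CPM ± 91.9 (2.93 ± 0.26), and the glial gene Cdh19 (2.36 ± 0.21) rose. Fibroblast markers fell, with a median of −1.44, 14 of 16 lower over all genes and 16 over the list alone (adjusted p = 2.94e-10; adjusted p = 0.617 with an estimated correlation). Fbln1 went from 111 CPM ± 17.1 to 24.6 CPM ± 3.20 (−2.18 ± 0.18), with Cd34 (−1.53 ± 0.15) and Clec3b (−1.41 ± 0.15). Other extracellular matrix genes fell, with a median of −1.29, 19 of 34 lower and 24 over the list alone (adjusted p = 3.39e-09; adjusted p = 0.617 with an estimated correlation), Fmod among them (−2.23 ± 0.23) and the laminin Lama4 (−1.12 ± 0.11). Collagens fell, with a median of −1.58, 8 of 19 lower and 2 higher, and 12 lower over the list alone (adjusted p = 0.00314; adjusted p = 0.709 with an estimated correlation; −0.87 without IgG replicate 2). Col14a1 fell by 1.83, while the fibrillar Col3a1, from 2173 CPM ± 1426 to 395 CPM ± 161 (−2.46 ± 0.58, adjusted p = 0.0176), and Col6a1 (−1.58 ± 0.38, 0.0191) lost the call without anti-IL-9 replicate 2 (−2.10, 0.087 and −1.20, 0.0805). Crosslinking and remodelling genes fell, with a median of −1.06, 12 of 30 lower and 14 over the list alone (adjusted p = 6.28e-05; adjusted p = 0.622 with an estimated correlation; −0.70 without IgG replicate 2), with Mmp3 at −1.27 ± 0.20 and Ctsk at −1.86 ± 0.34.

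Mesothelial markers fell, 8 of 8, with a median of −4.12 (adjusted p = 1.11e-07; adjusted p = 0.617 with an estimated correlation). Macrophage markers fell, with a median of −1.65, 13 of 16 lower and 14 over the list alone (adjusted p = 1.44e-07; adjusted p = 0.617 with an estimated correlation), with the complement gene C1qb at −1.65 ± 0.21 and Csf1r at −1.66 ± 0.24. Endothelial markers fell, with a median of −0.94, 12 of 15 lower and 1 higher, and 14 lower over the list alone (adjusted p = 1.3e-06; adjusted p = 0.617 with an estimated correlation). The gene of von Willebrand factor, Vwf, went from 116 CPM ± 21.1 to 25.2 CPM ± 0.724 (−2.20 ± 0.19), Pecam1 at −1.04 ± 0.15 and Cdh5 at −1.20 ± 0.17. White adipocyte markers fell, with a median of −0.87, 10 of 16 lower and 1 higher, and 14 lower over the list alone (adjusted p = 0.00019; adjusted p = 0.617 with an estimated correlation), with Adipoq at −0.97 ± 0.19 and Lipe at −0.92 ± 0.18. Contractile genes had a median of 0.96 and 14 of 18 higher over all genes and over the list alone (adjusted p = 0.000588; adjusted p = 0.622 with an estimated correlation). Tagln went from 62.7 CPM ± 12.6 to 148 CPM ± 4.79 (1.24 ± 0.18), Csrp1 at 1.42 ± 0.20 and Tpm2 at 1.36 ± 0.20. Skeletal muscle genes had a median of 2.85 and 12 of 16 higher, 13 over the list alone (adjusted p = 0.000222; adjusted p = 0.617 with an estimated correlation), with Mylpf at 2.72 ± 0.34 and Myh1 at 4.62 ± 0.58.

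Cytokines and chemokines fell, with a median of −1.0 and 7 of 18 lower over all genes and over the list alone (adjusted p = 0.00155; adjusted p = 0.622 with an estimated correlation), Cxcl12 (−1.18 ± 0.17) and Ccl6 (−1.97 ± 0.29) among them. Oxidative phosphorylation genes had a median of −0.53, 34 of 34 negative and 0 called (adjusted p = 0.000273; adjusted p = 0.709 with an estimated correlation), and fatty acid oxidation genes −0.60 with 3 lower and 1 higher (adjusted p = 0.00179; adjusted p = 0.709 with an estimated correlation). These medians were −0.22 and −0.27 without anti-IL-9 replicate 1 and −0.88 and −1.04 without anti-IL-9 replicate 2. Circadian clock genes had a median of −0.47 with 5 lower and 1 higher of 16 (adjusted p = 0.0135; adjusted p = 0.617 with an estimated correlation), with Dbp at −1.06 ± 0.13. TGF-beta signalling had a median of −0.04 with 8 of 23 lower (adjusted p = 0.0231; adjusted p = 0.709 with an estimated correlation; 0.000884 and 0.147 without IgG replicate 2, −0.08 and 0.0638 without anti-IL-9 replicate 2, and −0.29 without anti-IL-9 replicate 1), with the receptor Tgfbr2 at −1.33 ± 0.16 and Tgfbi at −1.06 ± 0.17. Neutrophil and monocyte markers had a median of −1.69 with 5 of 6 lower (adjusted p = 0.0252; adjusted p = 0.617 with an estimated correlation; 0.0564 without anti-IL-9 replicate 2). S100a8 there (−2.52 ± 0.62, adjusted p = 0.0208) lost its call in the joint fit (0.0602) and without IgG replicate 3 (0.0579) or anti-IL-9 replicates 1 (0.119) or 2 (0.0679). Brown adipocyte genes (−0.58, adjusted p = 0.0118; −0.24 and 0.168 without anti-IL-9 replicate 1, −1.05 without anti-IL-9 replicate 2) and proliferation (−1.01, 0 called, adjusted p = 0.0252; −0.23 and 0.215 without IgG replicate 2, 0.127 without anti-IL-9 replicate 2) passed, with adjusted p = 0.709 and 0.807 with an estimated correlation. T cell markers (1.99, 3 of 16 higher, adjusted p = 0.237; −0.37 without anti-IL-9 replicate 1), B and plasma cell markers (2.28, 4 of 11 higher, 0.145), mast cell and ILC2 markers (−1.27, 2 higher and 6 lower of 10, 0.43), cardiac muscle (−1.62, 3 lower and 2 higher of 10, 0.3), immediate early genes (0.47, 0.585), MHC class II (−0.26 with a mean of 0.28, 0.382), interferon response (0.05 with a test direction of lower, 0.923), erythrocyte (−0.07, 0.625) and mitochondrially encoded genes (0.01 with a test direction of lower, 0.625) did not pass.

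Whether anti-IL-9 moves the genotype's genes the other way was tested with the 100 genes nearest to significance in each direction. Those higher in non-stripped TKO aorta were called higher with anti-IL-9, not lower: 49 of 85 were positive, 34 rose and 7 fell, with a median of 0.26 (p = 6.9e-07, adjusted p = 4.1e-06; p = 0.123 with an estimated correlation). Skeletal muscle genes had medians of 3.27 and 2.85 in these comparisons, and Myh4, Mylpf and Pvalb are in the set. With the called genes only the median was −0.69, with a test direction of higher, and the set did not pass. Those lower in TKO had a median of −0.11 (adjusted p = 0.484). Wdfy1 and Pdpr were called in both comparisons in opposite directions, at 0.74 ± 0.23 (adjusted p = 0.0435) and −0.69 ± 0.20 (0.0388) with anti-IL-9. Wdfy1 lost that call with RLE factors (0.055), without any IgG replicate (0.0591, 0.102 and 0.144 for replicates 1, 2 and 3) and without anti-IL-9 replicate 2 (0.31, 0.227). Pdpr lost it without any IgG replicate (0.0649, 0.0543 and 0.109) or anti-IL-9 replicate (0.143 and 0.0598). Prune2 (2.97 ± 0.12, 0.000172) and Gm9855 (66 counts and 5, a ratio of 0.104 with an interval of 0.0328 to 0.256; 0.0478), chosen after their values were seen, moved as in the genotype comparison. Gm9855 lost its call in the joint fit (0.166) and without anti-IL-9 replicates 1 (0.185) or 2 (0.153). Across 14890 genes, which are not independent replicates, Pearson's r of the fold changes was 0.218 and Spearman's rho 0.182.

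The same sets were tested in the other tables. In stripped aorta the lower set was called lower with a median of −0.05 (57 of 99 negative, adjusted p = 0.000391; p = 0.176 with an estimated correlation), and the 9 called genes, Rpl30, Polr2k and Cpq among them, were all negative with a median of −0.93. The higher set had a median of −0.03 and a test direction of higher (adjusted p = 0.753). In fibroblasts the higher set was called higher with a median of 0.13 (61 of 85 positive, adjusted p = 0.0238; p = 0.313 with an estimated correlation). With the called genes only its median was 0.17 and it did not pass. The lower set had a median of 0.03 and a test direction of lower (adjusted p = 0.63). With the called genes only it was called lower, with a median of −0.37. Pearson's r with non-stripped aorta was −0.105 for stripped aorta and 0.0897 for fibroblasts, over 14703 and 14005 genes.

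Single cells ask which cell types carry these differences. Named classes held 80.5% of 43812 cells, and unnamed clusters held 11.2% and 27.7% of the Cre libraries and 21.8% and 24% of the TKO libraries. Log2 changes of shares are scaled by TMM and can differ in sign from the percents, as for macrophage-like and T-like cells. Fibroblast-like cells were 22% ± 3.74 in Cre and 27.1% ± 0.348 in TKO (0.54 ± 0.26; 0.18 at the finer clustering). Macrophage-like cells were 15.7% ± 1.80 and 13.4% ± 2.13 (0.01 ± 0.29), endothelial-like cells 8.21% ± 0.288 and 8.80% ± 0.0296. T-like cells were 4.15% ± 0.452 and 3.77% ± 1.05, B-like cells 6.84% ± 2.27 and 5.09% ± 0.401. Smooth muscle-like cells were 6.45% ± 2.72 and 3.62% ± 0.410, and NK-like cells 1.48% ± 0.194 and 0.798% ± 0.0707 (−0.66 ± 0.28). edgeR called 0 of 17 shares, with 0 at an unadjusted p under 0.05 and a lowest adjusted p of 0.885, and no other tool was run on shares. The scaled change of NK-like cells turned to 0.44 under the stricter cell filter, and that of T-like cells (0.09) to −0.15 under it and to −0.16 at the finer clustering. Unnamed cluster 8, nearest to fibroblasts and with high doublet scores, held 2.34% and 3.14% of Cre and 5.71% and 4.94% of TKO libraries. Unnamed cluster 10, nearest to T cells but with B cell markers too, held 0.504% and 7.96% of Cre and 3.02% and 6.07% of TKO libraries. These were 73 and 520 Cre and 464 and 451 TKO cells, against 647 and 250 Cre and 693 and 225 TKO cells named T-like. All values of T-like cells therefore leave out a part that differs between libraries.

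**Figure D5:**
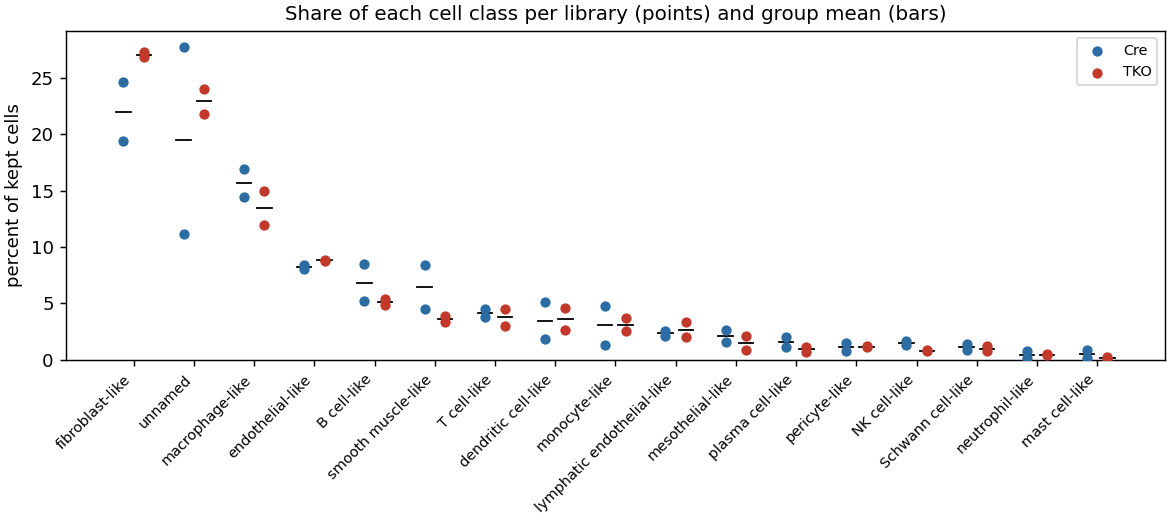
Percent of kept cells (vertical axis) in each class (horizontal axis) in 2 Cre and 2 TKO single-cell libraries, with points for libraries and bars for group means. Fibroblast-like cells make up 22% of Cre and 27.1% of TKO cells on average, and no share passed the test.

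Fibroblast-like cells fell into clusters that libraries filled unequally. Cluster 1, marked by Fmod, Thbs4 and Comp, matrix genes of tendon-like and adventitial cells, held 19.1% and 22.2% of the Cre and 56.5% and 50.02% of the TKO fibroblast-like cells. Cluster 0, marked by Pi16 and Cd248, held 47.1% and 64.8% of Cre and 25.5% and 40.3% of TKO. These shares were not tested for a difference. Macrophage-like cells were mostly cluster 2 in Cre replicate 1 (85.8%), against 24.4% in Cre replicate 2 and 47.5% and 36.6% in TKO, with cluster 5 holding most of the rest.

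In T-like cells Klf10 had 36 and 15 UMIs in Cre and 16 and 7 in TKO, or 26.9 CPM ± 5.02 against 17.3 CPM ± 4.47 (−0.68 ± 0.47, adjusted p = 1.00; −0.35 without TKO replicate 1). A tag at the 3′ end may lie outside the deleted part, in which case it checks nothing. Over all kept cells Klf10 was at 69.1 and 42.8 CPM in Cre and 66.4 and 65.4 CPM in TKO. Il9 had 0 UMIs in all 114998 barcodes, which in T-like cells allows shares with a UMI of up to 0.464% and 1.2% in Cre and 0.433% and 1.33% in TKO. Cd3e, a T cell gene, was read in 67.9%, 63.2%, 59.2% and 56.9% of T-like cells (Cre, then TKO) and in 1.51%, 8.62%, 6.36% and 6.07% of fibroblast-like cells, at median depths of 2184, 1796, 1311 and 1377 UMIs against 2499, 1501.5, 1511 and 1338.

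Collagen and other matrix genes were higher in TKO cells of classes that should hold little of them. In B-like cells Col1a1 rose from 70.7 CPM ± 22.2 to 401.4 CPM ± 7.33 (2.56 ± 0.29, adjusted p = 0.00347, n = 2 per group), with the proteoglycans Aspn (3.18 ± 0.38, 0.00401) and Lum (2.77 ± 0.36, 0.00633). In monocyte-like cells Col1a1 (2.90 ± 0.34), Fstl1 (2.92 ± 0.36) and Ogn (2.81 ± 0.35) rose and the collagenase Mmp13 fell from 142 CPM ± 13.8 to 15.7 CPM ± 5.41, each at adjusted p = 0.00101. This class held 1536 cells and was marked by Mmp12, Chil3 and Cx3cr1. At the finer clustering a cluster marked by Mmp12 and Cx3cr1 was named macrophage-like, and 675 cells were named monocyte-like. The class may therefore mix both, and a change in that mix was not tested. In lymphatic endothelial-like cells Sfrp2 (3.24 ± 0.40), Fst (3.29 ± 0.41) and Aspn (2.60 ± 0.34) rose, each at 0.0164. The B cell gene Cd79a was read in 3.47% and 24.4% of Cre and 11% and 17.4% of TKO fibroblast-like cells, against 78.8%, 76.0%, 65.5% and 66.4% of B-like cells (median depths 1749.5, 1552.5, 1327.5 and 1232 UMIs). In B-like cells Reg1, Clps and Cpb1, genes of the exocrine pancreas, had 451, 578 and 568 UMIs in Cre and 0 in TKO, at least 85.6-fold, 110-fold and 108-fold lower (adjusted p = 0.00137 each). Without Cre replicate 1 these bounds fell to 46.2, 54.1 and 50.2. Pnlip, Ctrb1, Cela1, Try4 and Prss2, also genes of the exocrine pancreas, were among the other genes called lower in B-like cells. How their RNA came to be read in these Cre cells was not tested. In monocyte-like cells Try4 and Prss2 had 362 and 409 UMIs in Cre and 0 in TKO, at least 61.9-fold and 69.9-fold lower (0.00101 each), but only 11.4-fold for both without Cre replicate 1, and DESeq2 did not call them (adjusted p = 0.553 and 0.588).

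Gm2682, a predicted gene that starts at 60120540 of chromosome 15, was lower in TKO in NK-like cells (163 and 2 UMIs, 29.1-fold lower with an interval of 7.94 to 243; adjusted p = 0.0109) and T-like cells (257 and 4 UMIs, 43.9-fold, 16.9 to 162; 0.0298). The antibody segment Igkv16-104 fell in plasma-like cells (412 and 0 UMIs, at least 66.8-fold; 0.0145). edgeR called 31 genes higher and 18 lower in B-like, 39 and 6 in monocyte-like, 5 and 0 in lymphatic endothelial-like, and 0 and 1 in each of NK-like, T-like and plasma-like cells. It called 0 in fibroblast-like cells (611 at an unadjusted p under 0.05, 66 by DESeq2), macrophage-like (433, 21), endothelial-like (287, 2), mesothelial-like (149, 2), dendritic-like (545, 0), smooth muscle-like (236, 0), pericyte-like (42, 0) and Schwann-like cells (91, 0). Aspn and Sfrp2 were called in 3 classes each. Without Cre replicate 1 the monocyte-like calls of Col1a1 (0.34), Fstl1 (0.744), Ogn (0.754) and Mmp13 (0.34) and the NK-like call of Gm2682 (0.424; 0.916 by DESeq2) were lost. The calls were also lost for Fst without TKO replicate 1 (0.459) and by DESeq2 (0.0698), for Aspn in lymphatic endothelial-like cells without high doublet scores (0.0542), for Gm2682 in T-like cells without TKO replicate 2 (0.225) and without high doublet scores (0.0659), and for Igkv16-104 without TKO replicate 1 (0.0986).

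Within fibroblast-like cells, collagens had a median of 0.27 in TKO, 14 of 19 positive and 2 higher over the list alone (adjusted p = 1.03e-06; adjusted p = 0.576 with an estimated correlation; 0.11, 0.0722 without Cre replicate 2 and 0.44 without Cre replicate 1). Contractile genes had a median of 0.64, 17 of 17 positive (adjusted p = 8.63e-09), cardiac genes 2.30, 7 of 7 positive (2.92e-10), erythrocyte genes 1.02, 6 of 6 positive (8.63e-09), and fibroblast markers −0.60, 12 of 16 negative (1.42e-05), each at adjusted p = 0.576 with an estimated correlation and called whichever library was left out. The contractile median was 0.13 and 1.04 without TKO replicates 1 and 2, and that of fibroblast markers −0.36 without Cre replicate 1. The erythrocyte gene Hbb-bs was read in 33.5% and 25.8% of Cre and 87.5% and 35.6% of TKO fibroblast-like cells. Other extracellular matrix genes (0.17, adjusted p = 0.00301; −0.04 and 0.444 without Cre replicate 2, 0.35 without Cre replicate 1), TGF-beta signalling (0.24, 0.00329; 0.15, 0.248 without Cre replicate 2 and 0.07, 0.0549 without TKO replicate 2), macrophage markers (0.62, 3.09e-05; 0.28, 0.0534 without TKO replicate 1) and endothelial markers (0.67, 0.00215; 0.29, 0.538 without Cre replicate 1, 1.24 without Cre replicate 2 and 0.38, 0.36 without TKO replicate 1) lost the call. So did fatty acid oxidation genes (−0.21, 0.00392; 0.3 without Cre replicate 2, 0.273 without TKO replicate 1, −0.37 without Cre replicate 1 and −0.44 without TKO replicate 2) and neutrophil markers (0.80, 0.00392; 0.53, 0.261 without Cre replicate 1, 1.99 without Cre replicate 2 and 0.148 without TKO replicate 2). These 6 lists had adjusted p = 0.576 to 0.58 with an estimated correlation. T cell markers (0.66, adjusted p = 0.000806) and MHC class II (0.36, 0.0301; −0.06, 0.281 without TKO replicate 2) turned without Cre replicate 1, to −0.39 and −0.57, and were at 2.44 and 2.73 without Cre replicate 2 (adjusted p = 0.788 and 0.846 with an estimated correlation).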

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

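The counts of called lists over splits of the samples were planned, and the tests of the 3 patterns weighed here and the counts of called genes over splits were chosen after the results were seen.

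In the bulk tables of TKO and Cre, genes within 20 Mb of Klf10 on chromosome 15 differed more often than genes elsewhere, with the highest share among 71 windows in each, but ranked 10 with anti-IL-9; in single cells the window ranked 1 in endothelial-like, fibroblast-like, lymphatic endothelial-like and mesothelial-like cells and 26 in B-like, 29 in monocyte-like and 35 in plasma-like cells, with 0 such genes in pericyte-like cells by edgeR. Reads shared with paralogs or pseudogenes are argued against as the whole cause, since the odds ratio in fibroblasts was 4.69 without ribosomal protein genes, predicted genes and pseudogenes and 4.77 with them. A segment of another strain carried with the Klf10 allele stays open, although the labels give C57BL/6 for every mouse: of the window's genes under an unadjusted p of 0.05 in bulk fibroblasts, 80% had the same sign in single fibroblast-like cells, against 57.7% elsewhere (one-sided Fisher's exact test, p = 0.00972). The shares were 64% against 48.6% for stripped aorta and 42.3% against 51.4% for non-stripped aorta (one-sided Fisher's exact test, p = 0.092 and 0.868). The genotype's own effect on these neighbours also stays open, untested. It would keep signs between tables of TKO and Cre as well, so the shares of signs cannot tell it from a segment.

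With anti-IL-9, neural genes were higher while fibroblast, mesothelial and macrophage genes were lower. A dilution of all other tissue alike is argued against, since the contractile median lay 2.40 above the fibroblast median on the log2 scale. Neuron cell bodies in the tissue taken stay open: Snap25, Th, Dbh, Prph, Uchl1 and Tubb3 rose with a median of 3.51, and 53.9% of the 1116 genes at least 4-fold higher were under 1 CPM in the single-cell libraries, against 15.7% of 15015 genes tested. Less adventitia relative to muscular wall stays open as well, with a median of −1.06 for genes specific to fibroblast-like cells, −1.96 for macrophage-like, −0.72 for mesothelial-like and −0.29 for lymphatic endothelial-like cells, against 0.97 for smooth muscle-like cells. Other classes, not part of that test, went both ways. Medians were 1.83 for Schwann-like and 2.07 for B-like cells, against −0.70 for endothelial-like and −0.93 for T-like cells. An effect of the IL-9 blockade itself, with 2 antibody libraries, stays open and untested.

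Matrix genes were higher in TKO leukocyte-like classes, and of 54 genes called higher in B-like or monocyte-like cells, 29 had their highest level in fibroblast-like cells. Doublets with fibroblasts are argued against as the whole cause in these 2 classes: at most 9.36% of the UMIs of the 29 genes in a TKO library lay in cells holding as many as the lower quartile of fibroblast-like cells, while 99.6% and 92.7% of TKO B-like cells held some. In dendritic-like cells such cells held 32.2% and 45.2% in TKO and 28.2% and 45.3% in Cre, so doublets stay open there in part. Free RNA in the droplets stays open: 100% of the genes tested were also higher in T-like (26), dendritic-like (29) and NK-like (12) cells, and 27 of 29 in macrophage-like cells. In B-like cells they reached 1.89% and 3.49% of the fibroblast-like level in Cre and 11.8% and 6.47% in TKO. T-like cells had 11.6% and 5.79% in TKO. Log2 ratio SDs were 0.490 to 0.814 in B-like, but 1.41 and 1.51 (9 genes) in Cre and 0.656 and 0.903 in TKO monocyte-like cells. Expression by TKO leukocytes stays open, untested.

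In non-stripped aorta the 10 splits of the 6 libraries cannot give a share under 0.05: the real split called 18 genes, the highest other 0, and 1 of 10 splits gave as many. In fibroblasts the real split called 10 genes, the highest other 0, and 1 of 10 gave as many. For lists the real splits called 9 and 8, the highest others 16 and 14, and 8 of 10 splits gave as many in both tables.

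Among the stripped Cre libraries, groups of 4 tested for a sample far from the others, 5 of 59 values stood apart, where chance gives about 1 in 20. Replicate 1 had 153 CPM of Pnpla2 against 201 to 209 in the others. Replicate 1 also had 21.9 CPM of Ucp1 against 97.3 to 109.6. The endothelial markers of replicate 1 had a mean log2 CPM of 4.72 against 5.52 to 5.65. Its fatty acid oxidation genes were at 5.90 against 6.34 to 6.37. Replicate 4 had 17.6 CPM of Cdh19 against 10.6 to 11.04. Pdpr differed between tissues in its genotype effect, by 1.92 on the log2 scale, as tested by the interaction.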

How the results depend on the processing

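Removal of cells with a doublet score over 0.15 and the sets of called genes alone were chosen after seeing the data, and the other alternatives here were planned. Across 139 gene results in bulk tissue, 424 of 556 values under other settings kept direction and side of the threshold, 8 lost the call and 124 gained one. With a library left out, 644 of 781 did so, 114 lost the call, 21 gained one and 2 turned. Across 83 lists, RLE factors changed 0 calls by camera, while an estimated correlation ended all 53, and with a library left out 376 of 473 values kept direction and side of the threshold, called or not, 38 lost a call, 21 gained one and 38 turned. Of the called lists, 4 of 9 in non-stripped aorta, 7 of 17 in stripped aorta, 4 of 8 in fibroblasts and 15 of 19 with anti-IL-9 passed whichever library was left out. Across 20 genes in single cells, 74 of 80 values under other settings and 68 of 78 with a library left out kept direction and side of the threshold. The cause was not tested except where the setting itself shows it. Where a left-out library leaves 1 sample in a group, that sample is assumed to vary like the other group.

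Counts of called genes depended on the test and the filter. With DESeq2, no low-count filter and the joint fit, non-stripped aorta had 685, 671 and 601 genes higher (9 as reported; 0 to 397 with a library left out) and 117, 95 and 95 lower (9; 0 to 89). Stripped aorta had 309, 47 and 249 higher (2; 0 to 26) and 229, 17 and 132 lower (2; 0 to 5), and fibroblasts 149, 218 and 24 higher (5; 2 to 5) and 268, 464 and 42 lower (5; 1 to 5). With anti-IL-9, 2892 genes were lower with no filter, 2757 in the joint fit and 647 at an absolute log2 fold change of at least 1 (1815; 1048 to 1733). The tissue difference had 495 genes higher with DESeq2 and 87 with no filter (1; 0 to 99), and 383 and 72 lower (0; 0 to 143). For the genes nearest to significance in non-stripped aorta, an estimated correlation ended the calls of the higher set with anti-IL-9 (median 0.26) and in fibroblasts (0.13) and of the lower set in stripped aorta (−0.046). The called genes alone ended the first 2, at −0.69 and 0.17, and brought a call of the lower set in fibroblasts, at −0.37.

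With a library left out, Klf10 in fibroblasts ranged from −0.11 to 0.031. The following lists turned in the direction of their test, some with a median that kept its sign. In non-stripped aorta the medians ranged from −0.021 to 0.066 for crosslinking, −0.048 to 0.24 for other matrix, 0.011 to 0.13 for collagens, −0.32 to 0.27 for interferon response, −0.018 to 0.24 for immediate early genes and −0.032 to 0.69 for erythrocyte markers. In stripped aorta they ranged from −1.0 to 0.63 for immediate early genes, −0.26 to 0.13 for other matrix, −0.26 to 0.11 for interferon response, −0.081 to 0.98 for neutrophil and monocyte markers, −0.12 to 0.89 for mitochondrially encoded genes and −0.39 to 0.17 for collagens. In fibroblasts the IL-9 list ranged from −0.046 to 0.25, interferon response from −0.16 to 0.82, TGF-beta signalling from 0.0068 to 0.042, MHC class II from −0.10 to 0.18 and cytokines from −0.62 to 0.11. With anti-IL-9, interferon response ranged from −0.16 to 0.27, erythrocyte markers from −0.80 to 0.32, T cell markers from −0.37 to 2.80 and MHC class II from −1.13 to 0.12. In single fibroblast-like cells Klf10 ranged from −0.33 to 0.33, T cell markers from −0.39 to 2.44 and MHC class II from −0.57 to 2.73.

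Of the class shares, 0 passed under any setting by edgeR. As log2 changes scaled by TMM and with a library left out, the B-like share (−0.17) ranged from −0.33 to 0.044, the macrophage-like (0.01) from −0.19 to 0.23, the T-like (0.09) from −0.15 to 0.32 and the unnamed (0.39) from −0.19 to 1.44. At least 1000 genes and at most 5% mitochondrial UMIs gave 0.44 for NK-like and −0.15 for T-like cells, and resolution 2.0 gave −0.62 for B-like and −0.16 for T-like cells. That stricter filter left no class with enough cells in every library, so its gene test gave no value. Keeping doublets was not run apart, since the caller marked none.

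In single cells the calls summed over classes, with a gene counted in each class that called it, numbered 102, against 166 with DESeq2, 1604 with no low-count filter and 160 to 3379 with a library left out. With no filter and with a library left out, the counts were 194 and 46 to 242 in B-like cells (49 as reported), 132 and 1 to 206 in monocyte-like (45), 82 and 5 to 74 in lymphatic endothelial-like (5), 36 and 2 to 63 in NK-like (1), 114 and 0 to 118 in plasma-like (1) and 104 and 0 to 159 in T-like cells (1). In classes with 0 calls by edgeR they were 188 and 0 to 159 in dendritic-like, 119 and 0 to 437 in endothelial-like, 252 and 0 to 754 in fibroblast-like, 220 and 0 to 632 in macrophage-like, 41 and 0 to 88 in mesothelial-like, 20 and 2 to 25 in pericyte-like, 32 and 0 to 19 in Schwann-like and 70 and 0 to 422 in smooth muscle-like cells. DESeq2 called 2 in endothelial-like, 66 in fibroblast-like, 3 in lymphatic endothelial-like, 21 in macrophage-like, 2 in mesothelial-like, 12 in monocyte-like, 0 in NK-like and 19 in plasma-like cells. Without high doublet scores NK-like cells had 2, plasma-like 22 and T-like 0.

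Single-cell libraries share the numbers 1 and 2 in the labels. With the number as a replicate block, the calls summed over classes numbered 709: 221 in B-like, 4 in dendritic-like, 21 in endothelial-like, 31 in fibroblast-like, 80 in lymphatic endothelial-like, 16 in macrophage-like, 35 in mesothelial-like, 77 in monocyte-like, 22 in NK-like, 32 in plasma-like, 9 in Schwann-like, 4 in smooth muscle-like and 157 in T-like cells. The block gave −0.0011 for the macrophage-like share. Across genes, the difference between replicates 1 and 2 in Cre and that in TKO correlated at Pearson's r 0.0201 to 0.359 over classes. With only 2 pairs the numbers do not pair the samples, so this is a hint from the data and not the design. For bulk tissue, no paired analysis was possible because the labels share no replicate numbers between groups. Depth limits Il9 and Il9r in bulk tissue and Klf10 and Il9 in T-like cells.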

Other observations

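The tests in this part were chosen after the results were seen.

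Genes that differed in isolated TKO fibroblasts were looked up in single fibroblast-like cells, leaving out those within 20 Mb of Klf10. Of the genes nearest to significance and higher in isolated fibroblasts, 58 of 71 were positive in fibroblast-like cells, with a median of 0.42 (camera, a competitive set test, p = 2.05e-19 at the preset correlation; p = 0.0147 with an estimated correlation). Of those lower, 43 of 73 were negative, with a median of −0.05 (p = 0.00912; p = 0.118 with an estimated correlation). Across 11422 genes Pearson's r was 0.116 and Spearman's rho 0.109. The hypothesis that genes higher in isolated TKO fibroblasts are also higher in TKO fibroblast-like cells of whole aorta was thus met for the higher set at both correlations, and for the lower set at the preset one only. The single-cell comparison has 2 libraries per group, and fibroblast-like clusters were filled unequally by genotype.

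Dcn, a proteoglycan gene of fibroblasts, was read in 18.9% and 20.8% of Cre and 73.2% and 40% of TKO T-like cells, and Hbb-bs, a haemoglobin gene, in 42.2% and 30.8% of Cre and 93.1% and 36% of TKO T-like cells. The median depths of these cells were 2184, 1796, 1311 and 1377 UMIs. T-like cells were mostly cluster 11 in Cre replicate 1 (95.4%) and TKO replicate 1 (89.5%), and in Cre replicate 2 and TKO replicate 2 cluster 11 held 48.4% and 66.2% and cluster 29 held 51.6% and 33.8%. Dendritic-like cells were mostly cluster 15 except in TKO replicate 1, at 90%, 76.6%, 38% and 81.5%.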
